A study of Mus musculus with 2 samples.

How the data were processed

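H3K4me2 was measured by ChIP-seq in forebrain tissue of mouse embryos (strain B6NCrl, embryonic day 11.5) in 2 biological replicates of 1 group, each a pool of embryos of mixed sex. Per the labels, the assembly was mm10. Per the file records deposited with the samples, each replicate's peaks were called on its filtered alignments with 2 control files, the technical replicates of replicate 1 were called jointly, the pooled list was called on both replicates, and the replicated list was derived from the pooled list and the 2 replicate lists. The aligner, the peak caller, their versions and the threshold are not given in the sources used here, nor is the rule by which a pooled peak entered the replicated list. Alignments and signal tracks were not used here.

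The deposited signal of each peak is the enrichment that the authors' peak caller gave it, on a scale not stated. The deposited −log10 values are those of each peak's p and q, by the authors' peak caller. The deposited score is a display value of at most 1000 and was not used in any test. The scales of the lists may differ, so values were compared between lists only as ranks and as the −log10 q of matched sites. The lists reached down to weak calls: 5.42% of replicate 1's peaks and 4.78% of replicate 2's had a q above 0.05. No read number was in the files used, so depth, and with it the chance of missing weak peaks, is unknown. Replicate 1 had the lower −log10 q in 94.3% of the sites matched 1 to 1 (median 13.7 against 47.2).

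The replicated list was checked against the replicate lists. Of its 31520 peaks, 27424 (87.0%) were overlapped by peaks of both replicates at 50% of either peak, 3989 (12.7%) by replicate 2's peaks only, 96 by replicate 1's only and 11 by neither. All of its peaks were also in the pooled list. Peaks on the 19 autosomes, X and Y were analysed, and 12 replicated peaks on scaffolds were left out.

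Genes and TSSs were taken from the GENCODE mouse annotation, release 21, on GRCm38, the build of mm10. On the reference sequence 27437 of 27457 annotated start codons (99.9%) were ATG, and no peak reached past a chromosome end. There were 21829 protein-coding genes with 54327 TSSs. A gene was marked when a peak overlapped the 1 kb on either side of any TSS. Marked length was the number of bases under peaks within 5 kb of the gene's reference TSS, chosen by principal isoform and transcript support. Distal peaks lay over 1 kb from every protein-coding TSS and were counted for the gene with the nearest reference TSS within 100 kb. TSSs of non-coding genes were not considered, so some distal peaks may be promoters of such genes. The territory of a gene is the sequence that can be assigned to it. The CpG ratio (observed over expected) was taken over 1 kb centred on the reference TSS.

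Peaks were shared when the overlap was at least 50% of either peak. Chance levels came from 1000 random placements of peaks on the same chromosome outside assembly gaps of 100 bp or more. Gene lists (17 typed lists and all olfactory and vomeronasal receptor genes), motifs, tests and the rule for named genes were fixed before the data were examined. Marking was tested by Fisher's exact test against all other protein-coding genes. Marked length and distal peaks were tested by two-sided permutation tests with 100000 random gene sets drawn within 5 strata of CpG ratio and of territory length. P-values were adjusted by Benjamini-Hochberg over the 19 lists. A gene set test treats genes as units, so it describes these pooled tissues and not the spread between embryos. Motif matches on either strand in distal peaks were compared with 1 control window per peak, within 1 percentage point of its GC content and away from all peaks and TSSs, by an exact McNemar test adjusted over 13 motifs. The named genes were a fixed set of 28 and, per list, the 3 with most marked bases and up to 3 (alphabetical) with none. To these came the 10 with the longest peak within 1 kb of a TSS, the 10 with most distal peaks, and the nearest genes of the 5 strongest unshared peaks per replicate. The text gives part of them, and the genes named as unmarked members of a list were chosen after their values were seen.

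The steps were tested on simulated data. Of 5000 peaks, 60.9% were planted as shared and 61.0% were found. Of 400 random lists of 20 genes, 4.75% had a p under 0.05 for marked length, 5.00% for distal peaks (permutation test) and 2.25% for marking (Fisher's exact test). Lists of 20 genes with a planted 2-fold marked length were found in 100% of 100 trials and those with 3-fold distal peaks in 84.0%. Motif tests between sets of control windows had a p under 0.05 in 3.08% of 130 cases (exact McNemar test), and all 10 planted sets were found. Per gene, values were equal to a direct count in all 300 genes checked.

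The alternatives were an overlap of 1 base or of 50% of both peaks, the pooled list, each replicate's own list (leaving out the other), peaks at or above the list's median signal, TSS windows of 500 bp and 2.5 kb, backgrounds with and without matching, windows of 20 kb on either side, distal limits of 5 kb and 500 kb, and flanks 5 kb away as motif controls. Chosen after the data had been seen were replicated peaks overlapped in both replicates, gene sets drawn only from genes with a TSS peak, and motif controls matched on GC and repeats (within 10 percentage points). The share of 31-mers that occur once on the chromosomes was counted within 1 kb of TSSs. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 were used.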

Results

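Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark carried by promoters and by distal regulatory elements, was mapped by chromatin immunoprecipitation and sequencing in the forebrain of mouse embryos at embryonic day 11.5. At this stage the forebrain holds the telencephalon, which forms the cortex above and the basal ganglia below, and the diencephalon. There was 1 group with 2 biological replicates, each a pool of tissue from embryos of mixed sex. Replicate 1 pooled 109 embryos and was sequenced as 2 technical replicates. Replicate 2 pooled 88 embryos with 1 technical replicate. No other tissue, stage or treatment was compared, so the comparisons that the design allows are between the replicates and, within the group, between regions and groups of genes. The values were peak lists. Read numbers were not in them, so the depth of each library is unknown and no counting interval is given. On the 19 autosomes and chromosomes X and Y, replicate 1's list held 54676 peaks over 32.3 Mb and replicate 2's held 47279 peaks over 45.1 Mb. The authors' replicated list, which they derived from the pooled peaks and both replicate lists, held 31520 peaks over 40.2 Mb, or 1.52% of the assembled sequence. Unless stated otherwise, values come from this replicated list, and values given as mean ± SD come from the 2 replicates' own lists.

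The first question was where the mark lay. Promoters carried most of it. Of the 31520 peaks, 17169 (54.5%) lay within 1 kb of the transcription start site (TSS) of a protein-coding gene, against 4.14% when the peaks were placed at random on the same chromosomes, a 13.2-fold excess. A further 6.63% were centred in exons (random placement 4.22%), 20.8% in introns (41.1%) and 18.1% between genes (50.5%). The excess at TSSs and in exons was past all 1000 random placements, and so was the deficit in introns and between genes (permutation test, one-sided, p = 0.001 each, the smallest value 1000 placements can give). A peak within 1 kb of a TSS was not counted in the other classes, so the high TSS share lowers their shares by construction. The deficits are therefore not separate from the TSS excess, and the location of distal peaks alone was not tested. Peaks at TSSs were long and strong, with a median width of 1537 bp and a median signal of 24.1. The 14351 distal peaks had a median width of 571 bp and a median signal of 5.93. The signal is the authors' own value per peak, on a scale not stated. In the replicates' own lists the TSS share was 41.7% ± 3.13 (SD, n = 2), below that of the replicated list. Among replicated peaks at or above the median signal it was 84.4%.

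At the level of genes, 14265 of 21829 protein-coding genes (65.3%) had a peak within 1 kb of a TSS. Replicate 1's own list marked 65.6% of genes and replicate 2's 66.5%, and 97.6% of genes were in the same state in both. Marking followed the CpG content of the promoter. In 5 equal groups of genes by the ratio of observed to expected CpG around the TSS, from lowest to highest, 6.18%, 33.2%, 89.7%, 98.4% and 99.3% of genes were marked. The median marked gene had 2110 bases under peaks in the 10 kb centred on its reference TSS.

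**Figure D1:**
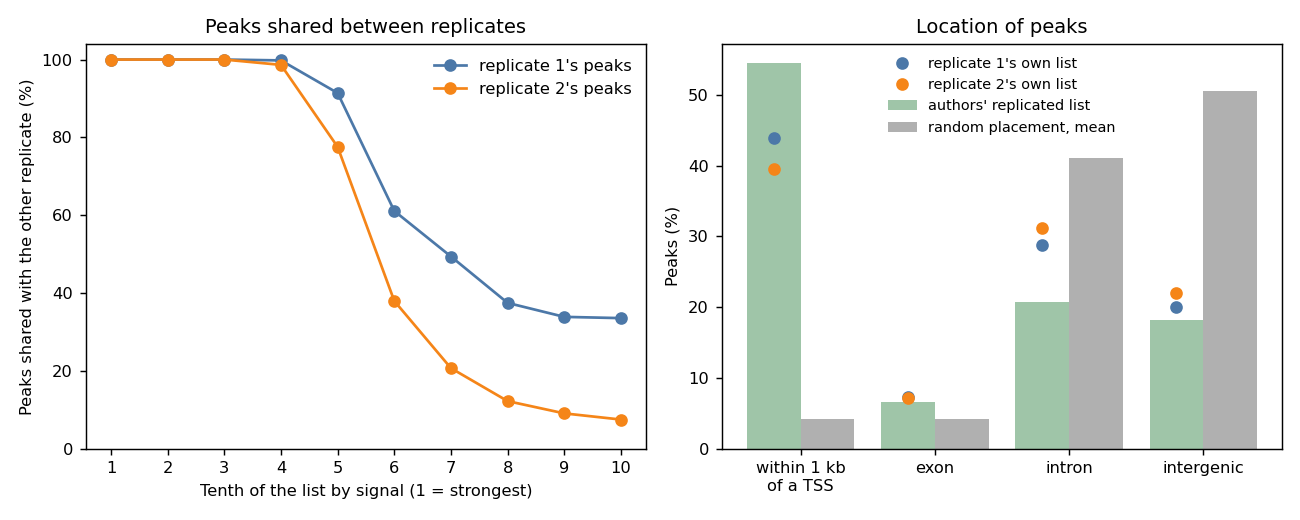
Left, percent of each replicate's peaks (y axis) that overlap a peak of the other replicate by at least 50% of either peak, in 10 equal groups of each list by signal from strongest to weakest (x axis). Right, percent of peaks (y axis) by location, as bars for the authors' replicated list and for the mean of 1000 random placements, with points for each replicate's own list. The strongest 3 groups were shared in full in both directions, and 54.5% of replicated peaks lay within 1 kb of a TSS against 4.14% at random.

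The next comparison asked which groups of genes had marked promoters. All 25 genes of telencephalic progenitors and patterning were marked, among them Foxg1, Emx1, Emx2, Pax6, Lhx2 and Sox2, transcription factors that build and pattern the telencephalon. All 18 subpallial and GABAergic genes were marked, including Dlx1, Dlx2, Dlx5, Dlx6, Gsx2, Ascl1 and Nkx2-1, regulators of the basal forebrain. The same held for the 18 pan-neuronal genes, the 25 genes of developmental signalling and the 20 housekeeping genes. Of the pallial and glutamatergic genes, 19 of 21 were marked, with Neurod6 and Nhlh2 left out. Of the genes of diencephalon, hypothalamus and eye, 18 of 19 were marked, with Otp left out. Among genes of the midbrain, hindbrain and spinal cord, 21 of 24 were marked, and among genes of mesenchyme, meninges and neural crest also 21 of 24. These 9 lists exceeded the share of all other protein-coding genes, which was about 65.3% beside each (Fisher's exact test, two-sided, Benjamini-Hochberg over 19 lists, adjusted p from 1.08e-04 to 0.0371). The pallial and the mesenchymal list lost this call in replicate 1's own list (85.7% and 83.3% against 65.5%) and among peaks overlapped in both replicates, and the mesenchymal list also with a TSS window of 500 bp. Among peaks at or above the median signal, the telencephalic list (88% against 57.8%) and the housekeeping list (90% against 57.8%) kept the call. The other 7 lost it, and the list of midbrain, hindbrain and spinal cord turned below (45.8% against 57.8%).

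Lower shares were found in 6 lists. Of the 39 Hox genes, which give positional identity to the trunk and hindbrain, 16 (41.0%) were marked. Of the 20 genes of blood and microglia, 5 were marked, and none of the 7 globin genes among them. Of the 21 terminal genes of liver, pancreas and muscle, 2 (9.52%) were marked, and of the 16 germline and pluripotency genes 4. Of 1091 olfactory receptor genes 3 were marked, and of 326 vomeronasal receptor genes 1, Vmn1r4, whose TSS lies 90 bp from that of Nt5c3. These lists fell below the share of the other genes (Fisher's exact test, two-sided, adjusted p at most 0.00365). The 26 regulators of mesoderm and endoderm (57.7%), the 17 endothelial genes (52.9%), the 16 surface ectoderm genes (12 marked) and the 16 glial genes (68.8%) did not differ from it (adjusted p from 0.370 to 1.00, Fisher's exact test). Against random genes of like CpG ratio, the pan-neuronal list was above (100% against 77.4%, permutation test, adjusted p = 0.00863). A peak at any TSS marked a gene, but sets were matched on CpG at the reference TSS and not on the number of TSSs. What the number of TSSs adds to this excess was not tested. The telencephalic, subpallial, signalling and housekeeping lists were also at 100%, but their matched genes stood at 91.0% or more, which left no room for an excess to pass the test. Not past it either were the lists of mesenchyme, meninges and neural crest (87.5% against 73.5%), pallial and glutamatergic genes (90.5% against 82.8%) and diencephalon, hypothalamus and eye (94.7% against 91.1%), and that of midbrain, hindbrain and spinal cord turned below (87.5% against 92.6%). The Hox (90.7% in matched genes), germline (83.5%), liver, pancreas and muscle (29.7%), olfactory (10.2%) and vomeronasal (8.96%) lists remained below (permutation test, adjusted p at most 0.0446), and the blood list did not differ from its matched sets (27.1%). The members of Hox and receptor lists are neighbours on the chromosome and share windows, so these p-values are too small for them. Other lists also hold some neighbours, such as Alb with Afp and Dlx5 with Dlx6. Their p-values may be too small as well. Around the TSSs of 108 of the 326 vomeronasal receptor genes, under 50% of 31-mers occurred once, so reads could often not be placed there, against 36 of 500 random genes and 26 of the 1091 olfactory receptor genes. The same held for the globin genes Hba-a1 and Hba-a2 and for Serpina1a of the liver list.

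The next comparison measured the length of the marked region. Genes of telencephalic progenitors and patterning had a mean of 8234 bases under peaks in the 10 kb around the TSS, 3.68 times the 2239 of random genes of like CpG ratio. In the replicates' own lists the mean was 7803 ± 865 (SD, n = 2). Lhx2, Otx1 and Meis2 were covered over the whole 10 kb. The developmental signalling genes had a mean of 5231 (2.35 times the matched sets), led by the Hedgehog receptor gene Ptch1 with 9803 and the Notch ligand gene Dll1 with 9521. Subpallial and GABAergic genes had 5322 (2.25 times), led by Olig2 with 9424, Dlx1 with 8600 and Slc32a1, the vesicular GABA transporter gene, with 8212. Replicate 1's own list gave this group 3409 bases and replicate 2's 5857. In the same order, they gave 3026 and 8439 at Slc32a1, 5308 and 8545 at Dlx1, and 7922 and 9362 at Olig2. Pallial and glutamatergic genes had 4132 (2.07 times), led by Lhx5 with 9688, Bcl11b with 7716 and Ebf3 with 7428. The means of the 2 replicates' own lists were 4835 ± 820 in the signalling list and 3787 ± 987 in the pallial list. None of 100000 random sets lay as far from the matched mean as any of these 4 lists (permutation test, two-sided, adjusted p = 2.71e-05, from the smallest p the sets can give). These 4 lists stayed above their matched sets under every alternative tried.

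Smaller excesses were seen in 5 further lists. The mean was 3041 bases in pan-neuronal genes (1.76 times the matched sets), 1940 in glial genes (1.64 times), 2774 in genes of mesenchyme, meninges and neural crest (1.62 times), 3482 in genes of diencephalon, hypothalamus and eye (1.54 times) and 3143 in housekeeping genes (1.35 times), with adjusted p from 2.28e-04 to 0.01 (permutation test). In the pan-neuronal list the neuronal tubulin gene Tubb3 led with 5738 bases. The glial mean rested on the transcription factor genes Nfib (9561) and Nfia (7819), while Mag and Plp1, genes of mature oligodendrocytes, had 0. The reference TSS of Mbp also had 0, but a peak covered another of its TSSs. Genes of midbrain, hindbrain and spinal cord matched their random sets, with 2230 against 2208 bases (adjusted p = 0.928, permutation test), and were led by Gata3 with 4229, Gata2 with 3950 and Egr2 with 3658. Below the matched sets were the Hox genes with 463 against 2173 bases, the germline and pluripotency genes with 330 against 1893, the olfactory receptor genes with 3.24 against 189.9 and the vomeronasal receptor genes with 6.82 against 174.9 (adjusted p at most 1.42e-04, permutation test). The lists of blood, endothelium, surface ectoderm, mesoderm and endoderm, and liver, pancreas and muscle did not differ from their matched sets (adjusted p from 0.109 to 0.636, permutation test). Among replicated peaks at or above the median signal, the mean of the diencephalic list (1892 against 1973 bases) and that of the mesenchymal list (1411 against 1461) turned below the matched sets. The glial list (1495 against 993) and the housekeeping list (2390 against 2039) stayed above but were no longer past the test. Under the same limit 3 more lists fell below the matched sets: midbrain, hindbrain and spinal cord (1051 against 1919), mesoderm and endoderm (598 against 1148) and endothelium (375 against 984.5). The glial, pan-neuronal and housekeeping lists also missed the test with windows of 20 kb on either side, and so did the diencephalic list in replicate 1's own list (2230 against 1819 bases).

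**Figure D2:**
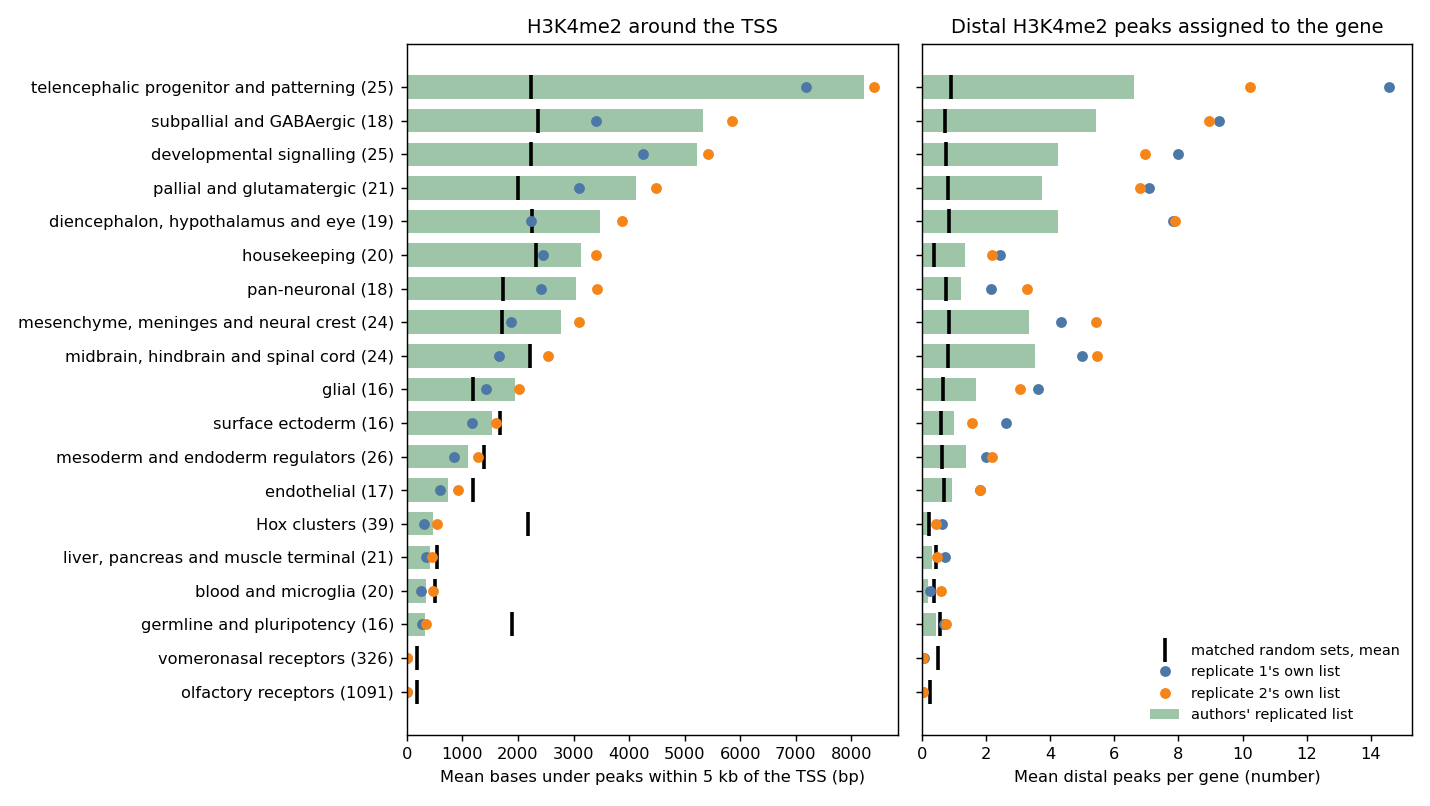
Left, mean bases under peaks within 5 kb of the TSS (x axis, bp), and right, mean number of distal peaks assigned to a gene (x axis), for the 19 gene lists (y axis, number of genes in parentheses). Bars are the authors' replicated list, points each replicate's own list, and black ticks the mean of 100000 random gene sets matched on CpG ratio (left) or territory length (right). Telencephalic genes reached 8234 bases against 2239 in matched sets, and Hox genes 463 against 2173.

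In genome build GRCm38 (mm10), the longest peak within 1 kb of a TSS was that of Pax6, the eye and forebrain regulator, on chromosome 2 from 105666750 to 105683600 (16851 bp). Next came Otx1 (chromosome 11, 21992790 to 22009120, 16331 bp), Emx2 (chromosome 19, 59454391 to 59470432, 16042 bp) and Lhx2 (chromosome 2, 38344775 to 38360236, 15462 bp). Zic2 (15234 bp), Six3 (14645 bp), Meis2 (13523 bp) and Dmrta2 (13076 bp) followed, together with 1 peak of 13670 bp at Skida1 that also reached within 1 kb of a TSS of A930004D18Rik. These widths were near those in replicate 2's own list. In replicate 1's own list the widest peak was 12932 bp at Otx1, 8880 at Lhx2, 7018 at Skida1 and 6732 at Zic2, with 5139 at Pax6, 4306 at Emx2, 4107 at Meis2, 3532 at Dmrta2 and 3165 at Six3. Foxg1, the telencephalic regulator on chromosome 12, had 7358 ± 1194 marked bases (SD, n = 2) in pieces, with the TSS under a peak from 49381481 to 49384918. Marked bases were 6427 ± 684 at Emx1, 8997 ± 1385 at Otx2, 7611 ± 1739 at Sox2 and 7689 ± 1348 at Six3. At the subpallial genes they were 6926 ± 2289 at Dlx1, 5015 ± 1274 at Dlx2, 3705 ± 1246 at Dlx5, 5606 ± 2630 at Dlx6, 4266 ± 2012 at Gsx2, 5836 ± 1006 at Ascl1 and 3010 ± 2606 at Nkx2-1. At the pallial genes they were 5173 ± 1283 at Neurog2, 3636 ± 1236 at Eomes and 2757 ± 2001 at Tbr1, so that the spread between replicates was near the value itself at Nkx2-1 (1167 bases in replicate 1 and 4853 in replicate 2) and at Tbr1 (1342 and 4172). The housekeeping genes Gapdh and Actb had 4346 ± 693 and 2468 ± 653, so that Gapdh lay above Dlx5, Eomes and Tbr1, as it did in each replicate's own list and in the replicated list. Alb, Gata1, Hbb-bs and Pecam1, genes of liver, red cells and endothelium, had 0 in each list. The cardiac regulator Nkx2-5 had 205.5 ± 43.1 and the muscle regulator Myod1 1197 ± 578.

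The Hox clusters carried small, separate peaks. The replicated list covered 5.38% of the HoxA cluster (chromosome 6, 52153317 to 52265880), 1.60% of HoxB (chromosome 11, 96189316 to 96370752), 1.76% of HoxC (chromosome 15, 102916103 to 103039395) and 7.30% of HoxD (chromosome 2, 74663310 to 74767980). In the same order, replicate 1's own list covered 3.94%, 1.33%, 1.12% and 4.76%, and replicate 2's 5.95%, 1.94%, 2.35% and 8.64%. Hoxa7 (1530 bases), Hoxa1 (1401) and Hoxd1 (1329) were the most marked members, while Hoxa2, Hoxa9, Hoxa10, Hoxa11 and Hoxd10 had 0. Replicate 1's own list had 177 marked bases at Hoxa9, 159 at Hoxd10 and 155 at Hoxa11, and replicate 2's had none, so the means were 88.5 ± 125, 79.5 ± 112 and 77.5 ± 110 (SD, n = 2). By comparison, 19.8% of the 120 kb around Foxg1, 17.7% around Emx2 and 13.8% around Dlx5 and Dlx6 was under replicated peaks. Foxg1 and Emx2 are among the most marked genes, at percentiles 99.59 and 99.95 of marked bases. Over the assembled sequence the share was 1.52%, so HoxA and HoxD lay above it and HoxB and HoxC near it.

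**Figure D3:**
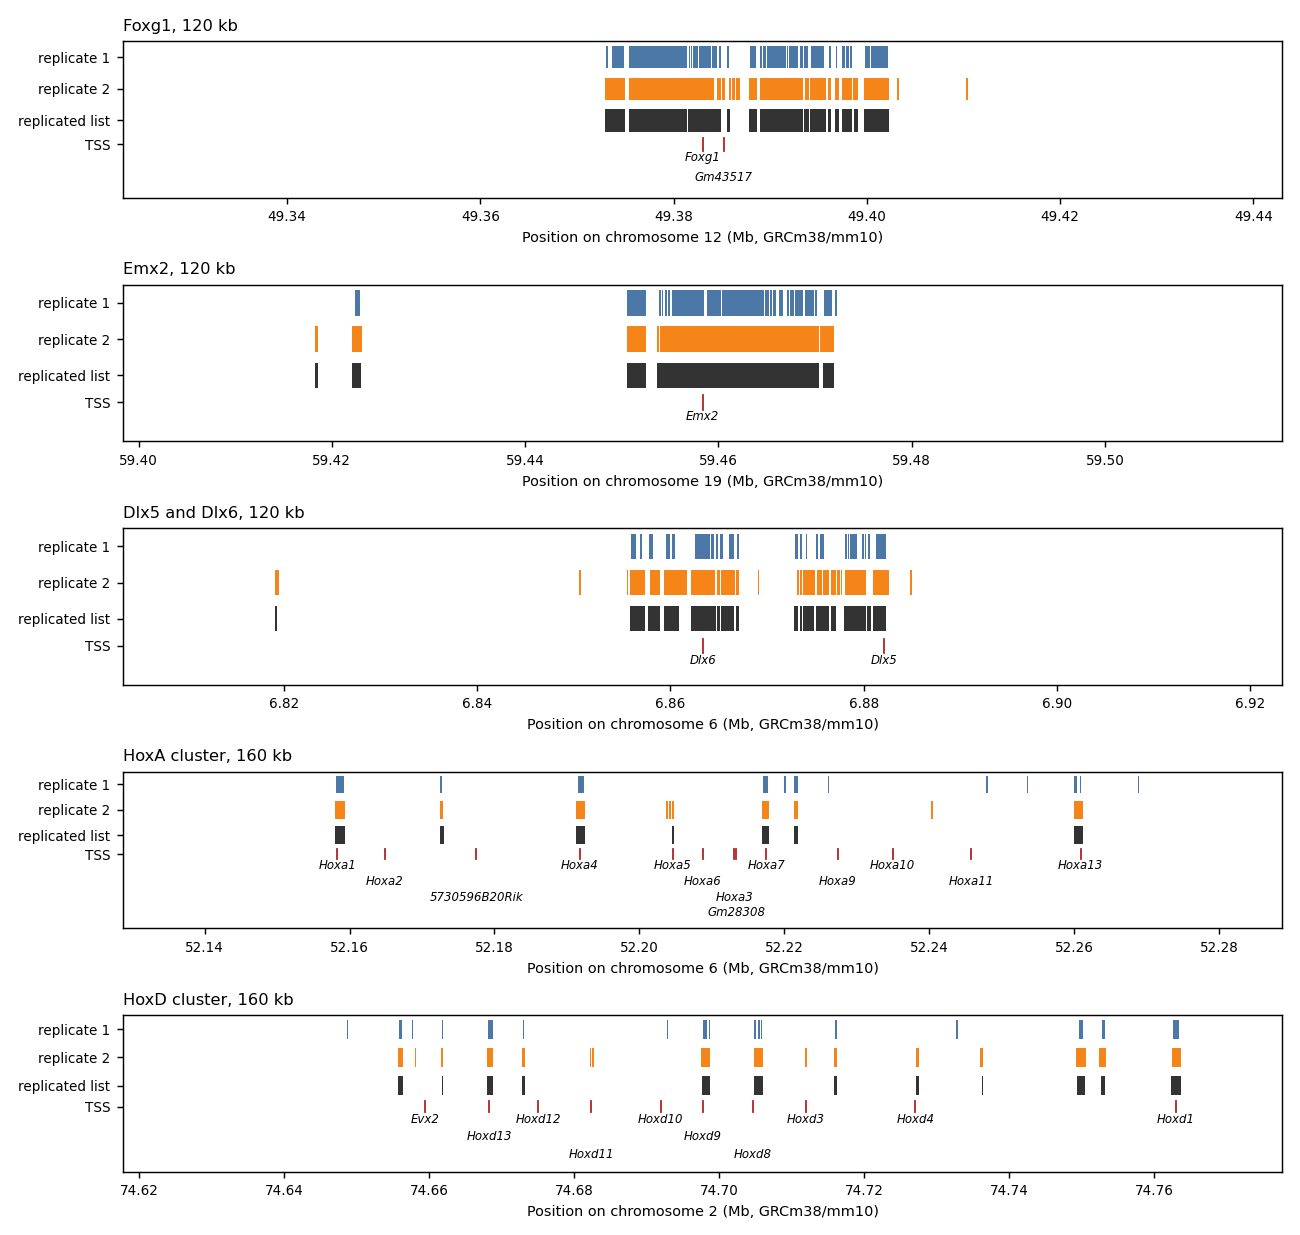
From top to bottom in each panel, peaks of replicate 1, of replicate 2 and of the authors' replicated list around Foxg1, Emx2, and Dlx5 with Dlx6 (120 kb each) and over the HoxA and HoxD clusters (160 kb each). The x axis is the position in Mb in GRCm38/mm10, and red ticks mark the reference TSSs of protein-coding genes. Replicated peaks covered 19.8% of the Foxg1 window and 3.78% of the HoxA window.

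Distal peaks were counted for the gene whose TSS was nearest, within 100 kb. Most genes (72.1%) had none, and the mean over all genes was 0.530. Telencephalic genes had 6.60 distal peaks each, 7.21 times the 0.915 of random genes with territories of like length, and 12.4 ± 3.06 in the replicates' own lists (SD, n = 2). Subpallial and GABAergic genes had 5.44 (7.56 times), developmental signalling genes 4.24 (5.53 times), genes of diencephalon, hypothalamus and eye 4.26 (4.98 times), pallial and glutamatergic genes 3.76 (4.62 times), genes of midbrain, hindbrain and spinal cord 3.54 (4.31 times) and genes of mesenchyme, meninges and neural crest 3.33 (3.92 times). All 7 reached an adjusted p of 2.11e-05, from the smallest p that 100000 sets can give (permutation test, two-sided). Housekeeping genes had 1.35 (3.44 times, adjusted p = 0.00293), glial genes 1.69 (2.49 times, adjusted p = 0.0199) and regulators of mesoderm and endoderm 1.38 (2.16 times, adjusted p = 0.0181, permutation test). Olfactory receptor genes had 0.0211 and vomeronasal receptor genes 0.0399, both below their matched sets (adjusted p = 2.11e-05, permutation test). The Hox genes had 0.256 against 0.240 (adjusted p = 0.901, permutation test), and the pan-neuronal, blood, endothelial, surface ectoderm, liver and germline lists did not differ either (adjusted p from 0.258 to 0.723, permutation test). The replicates' own lists reached down to weaker peaks and gave most lists more distal peaks per gene, such as 14.6 in replicate 1 and 10.2 in replicate 2 for the telencephalic genes. Pieces of a wide region at a TSS also counted as distal when over 1 kb from it. At Emx2 replicate 1 had 18 distal peaks and replicate 2 had 6. Many of the 18 lay within replicate 2's peak over the TSS (59453977 to 59470414). At Dlx5 both had 11. The share of such pieces in these values was not counted. Distal peaks within 5 kb of a reference TSS also count in marked length, so the measures are not fully separate. When distal meant over 5 kb from a TSS, telencephalic genes had 5.40 peaks against 0.696 and subpallial genes 2.89 against 0.539. The glial excess and that of mesoderm and endoderm were then lost. The latter was also lost in replicate 1's own list, in the pooled list and within 500 kb. The mesenchymal excess was lost among peaks at or above the median signal (0.167 against 0.132 peaks per gene), a pan-neuronal excess appeared in replicate 2's own list (3.28 against 1.49) and a surface ectoderm excess in replicate 1's (2.62 against 1.28).

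The genes with most distal peaks were Gse1, on chromosome 8, with 20, Bcor, Pax2 and Zfhx3 with 17 each, Sox2 with 16, Nr2f1 and Uncx with 15 each, 1700001O22Rik with 14, and Barhl2 and Pbx1 with 13 each. Several are transcription factor genes: Sox2 of neural progenitors, Nr2f1 of cortical patterning, Pax2 of the midbrain-hindbrain border and optic stalk, Barhl2 of the diencephalon and Uncx of the hypothalamus and somites. In the replicates' own lists Sox2 had 28.0 ± 2.83 and Nr2f1 26.0 ± 5.66 (SD, n = 2). Otx2 had 10 replicated distal peaks, Nkx2-1 had 9 and Dlx5 had 8.

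The sequence of distal peaks was then searched for 13 consensus motifs fixed beforehand, against 1 control window per peak of the same length, chromosome and GC content. Of 14351 distal peaks, 14246 had such a window. The motif of RFX factors was found in 1.46% of peaks against 0.372% of windows (3.92-fold), that of the insulator protein CTCF in 2.46% against 0.702% (3.51-fold), ETS in 1.75% against 0.877% (1.99-fold), POU in 7.92% against 4.19% (1.89-fold), the homeodomain core in 16.1% against 8.51% (1.89-fold), MEF2 in 1.14% against 0.695% (1.64-fold), TEAD in 11.7% against 9.89% (1.18-fold) and SOX in 57.2% against 50.3% (1.14-fold). These 8 were found more often (exact McNemar test, two-sided, Benjamini-Hochberg over 13 motifs, adjusted p at most 1.37e-04). Neighbouring distal peaks are not independent, so the p-values of these motif tests may be too small. The AP-1 motif was found less often, in 9.60% against 10.7% (exact McNemar test, adjusted p = 0.00236). Motifs of proneural bHLH, GATA, NFI and HNF4 factors did not differ (adjusted p from 0.176 to 0.864, exact McNemar test). The NFI motif was in only 0.126% of peaks and 0.112% of windows, too few for that test to decide. Its ratio was 1.67 in replicate 1's own list and 2.80 in replicate 2's. The RFX, CTCF, ETS and POU excess was present under every control and list that was tried, with an RFX ratio of 2.09 in replicate 1's own list. Against flanks 5 kb away that were not matched on GC, the ratio was 0.996 for SOX, 0.969 for the homeodomain core and 0.901 for MEF2, and the TEAD excess was lost (1.04). With control windows matched on repeats as well as GC, the TEAD excess was also lost (1.02), and the motifs of proneural bHLH (0.921) and GATA factors (0.900) were found less often. The bHLH motif was found more often against flanks (1.12), in the pooled list (1.04) and in the own lists of replicate 1 (1.08) and replicate 2 (1.06), so its direction depended on the control and the list. The control windows were not matched on CpG (median ratio 0.380 in peaks and 0.204 in windows), and the ETS consensus holds a CpG.

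**Figure D4:**
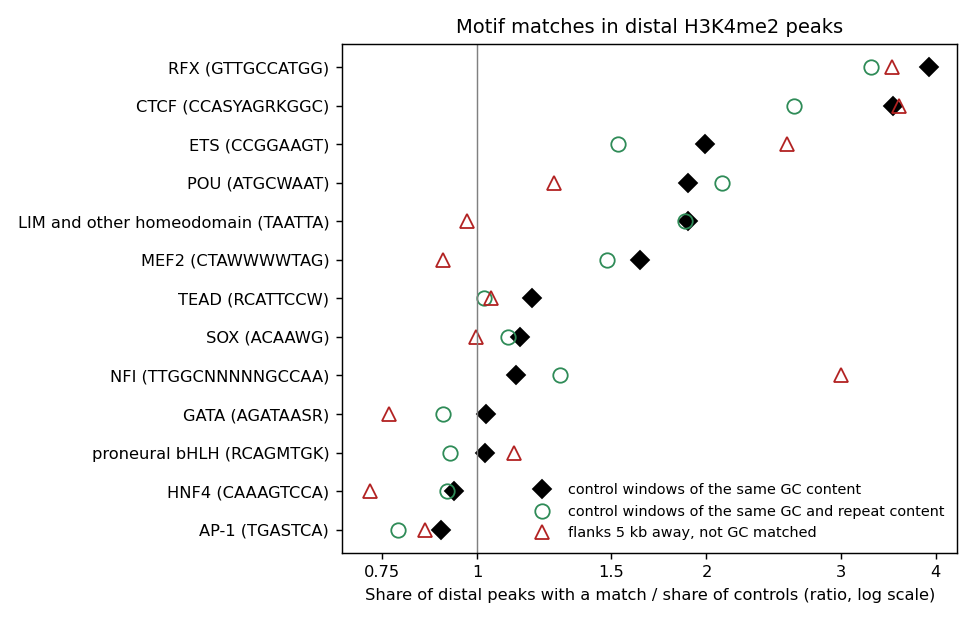
Ratio of the share of distal peaks with at least 1 motif match to that of control windows (x axis, log scale) for 13 motifs (y axis, consensus in parentheses). Diamonds are control windows of the same GC content, circles windows of the same GC and repeat content, and triangles flanks 5 kb away. RFX (3.92) and CTCF (3.51) lay highest, and homeodomain, SOX and MEF2 motifs lay below 1 only against flanks.

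The comparison between samples asked how far the replicates shared their peaks. With an overlap of at least 50% of either peak, 38635 of replicate 1's peaks (70.7%) were shared with replicate 2, against 2.31% at random, and 26652 of replicate 2's peaks (56.4%) with replicate 1, against 2.65% (permutation test, one-sided, p = 0.001, the smallest value 1000 placements can give). The shared 29.1 Mb made up 90.0% of replicate 1's bases and 64.6% of replicate 2's. In 10 equal groups of each list by signal, the strongest 3 were shared in full. The weakest was shared to 33.6% in replicate 1 and 7.51% in replicate 2. By this rule a short piece within a wide peak of the other list counts as shared. Replicate 1's weakest group had a median width of 155 bp, and 8630 of replicate 2's peaks held 2 or more of replicate 1's. The shares of the replicates are therefore not like measures of reproducibility. Over 17897 peaks matched 1 to 1, the signal of the lists was correlated with Spearman's rho = 0.912 and the width with rho = 0.897, both across peaks, which are not independent replicates. Replicate 1's peak was the shorter in 92.6% of these pairs. When 50% of both peaks had to overlap, 32.5% of replicate 1's peaks and 37.5% of replicate 2's were shared.

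Peaks without a partner at 50% of either peak were weak and lay away from promoters. In replicate 1, 16041 peaks (29.3%) had none. They had a median width of 155 bp, and 7.26% of them lay within 1 kb of a TSS, against 59.1% of its shared peaks. In replicate 2, 20627 peaks (43.6%) had none, with a median width of 235 bp and 11.6% near a TSS, against 61.0% of its shared peaks. The odds ratio between the replicates was 0.596 (Fisher's exact test, two-sided, p = 2.27e-45), but peaks of a library are not independent and each replicate is 1 library, so no difference between replicates is claimed. With 50% of both peaks required the order turned, to 32.1% in replicate 1 and 21.8% in replicate 2. Unshared peaks were also poor in CpG, with a median ratio of 0.194 in replicate 1 and 0.275 in replicate 2, against 0.525 and 0.530 in shared peaks. The strongest unshared peaks of replicate 1 lay nearest to Gpbp1, Alad, Robo2, Grrp1 and Foxf1, with signals from 6.87 to 7.83. Those of replicate 2 lay nearest to Rab6b, Cul3, Paip2b, Dgkb and Nebl, with signals from 16.7 to 18.2, on a scale that may differ. Those near Gpbp1, Robo2, Grrp1 and Dgkb overlapped a peak of the other replicate by at least 1 base, short of the 50% required. Only the peak near Alad was outside the replicated list.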

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

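No test in this part was chosen after the result was seen. Outside the 21 chromosomes analysed, 12 peaks of the authors' replicated list lay on unplaced or unlocalised scaffolds. They are set apart only because no comparison of the report used them, and nothing was tested on them. Their median signal was 6.85 and the strongest reached 12.8. None was at or above the median of the list.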

How the results depend on the processing

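Chosen after the data had been seen were the peaks overlapped in both replicates, the sets of genes with a TSS peak and the controls matched on GC and repeats. Under the alternatives, 468 of 558 values for single lists and motifs kept their direction and side of the threshold, 40 lost the call, 16 gained one in the same direction and 34 turned, 7 of them past the test in the main analysis and 27 not. Kept under all of them were the marked length of the telencephalic, subpallial, pallial and signalling lists, and the ratios of RFX (2.09 to 4.63) and CTCF (2.61 to 3.73). Except where the construction is named, the cause was not tested. With 50% of both peaks required, sharing was 32.5% in replicate 1 and 37.5% in replicate 2, and 32.1% and 21.8% of their unshared peaks lay near a TSS. With only peaks at or above the median signal, sharing was 94.7% and 86.0%, 13.6% and 22.8% of unshared peaks lay near a TSS, and the TSS share of the replicated list was 84.4%. That share was 44.8% in the pooled list, 39.5% to 43.9% without a replicate, 60.3% among peaks overlapped in both replicates and 60.6% with a window of 2500 bp. Lists marked above background numbered 9, but 2 among peaks at or above the median signal and 1 when matched on CpG ratio. The list of midbrain, hindbrain and spinal cord turned in both, to 45.8% against 57.8% and 87.5% against 92.6%. For marked length, peaks at or above the median signal gave 5 lists above and 7 below, where the main values were 9 and 4. There the diencephalic list (1892 against 1973 bases) and the mesenchymal list (1411 against 1461) turned. Without matching 7 lists were below. Among genes with a TSS peak, which leaves few genes of the lists below, 1 list was below for marked length and 0 for distal peaks. Motifs found less often numbered 1, but 0 among peaks at or above the median signal, 3 against flanks and 3 with controls matched on GC and repeats, and from 0 to 1 without a replicate. Against flanks the ratios for SOX (0.996), homeodomain (0.969) and MEF2 (0.901) turned. Flanks are not matched on GC by construction. The other values that turned had not been past the test. Glial marking was 62.5% among peaks overlapped in both replicates and with a window of 500 bp, 62.5% to 68.8% without a replicate and 50% at or above the median signal. Marking in surface ectoderm was 43.8% there and 75% against 75.4% when matched on CpG ratio. The marked length of midbrain, hindbrain and spinal cord was 1051 bases at or above the median signal, now past the test below its matched sets, 2120 among peaks overlapped in both replicates and 1659 to 2541 without a replicate. That of blood was 1331 with 20 kb on either side. Distal peaks per Hox gene were 0.333 in the pooled list, 0 at or above the median signal, 0.103 over 5 kb, 0.256 against 0.530 without matching, 0.250 among genes with a TSS peak and 0.436 to 0.641 without a replicate. They were 0.0588 in endothelium at or above the median signal, 0.50 in pan-neuronal genes over 5 kb and 0.55 in blood within 500 kb. Ratios were 0.943 for bHLH and 1.14 for HNF4 at or above the median signal, 0.995 for GATA and 1.16 for HNF4 among peaks overlapped in both replicates, and 0.942 to 1.01 for HNF4 without a replicate. Past the test in the turned direction were GATA against flanks (0.766), and bHLH (0.921) and GATA (0.900) with controls matched on GC and repeats. What depth limits was not tested, as it is unknown. Of 10 equal groups by signal, the weakest was shared to 33.6% in replicate 1 and 7.51% in replicate 2. Short pieces within wide peaks of the other list count as shared here.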

Other observations

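The tests of gene families, of chromosome X, of genes with a TSS peak alone and of CpG content at Hox and protocadherin genes were chosen after the results had been seen. Families were defined by the stem of the gene symbol, and 370 with at least 8 genes were tested against 10000 random sets of like CpG ratio. For marked length, 20 families lay above their matched sets and 13 below (permutation test, Benjamini-Hochberg over families, adjusted p under 0.05). Above were, for example, the transcription factor and chromatin families Lhx (5348 bases, 2.38 times the matched sets), Arid (4486, 2.11 times), Sox (4017, 1.97 times), Pou (2582, 1.90 times) and Cbx (4424, 1.72 times), and the Wnt receptor family Fzd (5200, 2.02 times). The non-clustered protocadherins (Pcdh, 4886 bases, 2.80 times) had the highest ratio of the 20, which also included Sema, Tubb, Arhgef and Cdk, with Pcdh7 at 7993 bases and Pcdh10 at 7695. The keratin family Krt lay below (166.4 bases against 804.9), and none of 34 Rhox genes, a reproductive homeobox cluster on chromosome X, was marked. Where the genes of a family are neighbours, as in such a cluster, they are not independent and the p-values of these tests are too small. Whether reads can be placed around the Rhox TSSs was not tested, so the lack of peaks there may not be a lack of the mark.

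When the comparison was limited to genes with a TSS peak, telencephalic genes had 3.40 times the marked bases and 5.84 times the distal peaks of matched genes. Housekeeping genes had 1.30 and 2.80 times, and genes of midbrain, hindbrain and spinal cord 1.02 and 3.79 times (permutation test, adjusted p = 0.0150 and 0.00645 for housekeeping, 0.879 and 4.29e-05 for midbrain, hindbrain and spinal cord). The glial excess was then no longer past the test (1.36 times the marked bases, adjusted p = 0.0699, and 2.20 times the distal peaks, adjusted p = 0.0516), nor was that of mesoderm and endoderm in distal peaks (1.70 times, adjusted p = 0.159, permutation test). Of the 39 Hox genes, the 16 with a TSS peak had 0.342 times the marked bases of matched genes.

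In the fifth of genes with the lowest CpG ratio, 6.18% had a TSS peak. The most marked of them was Kdm6b, a histone demethylase gene on chromosome 11, with 10000 of 10000 bases around its reference TSS. Nhlh1, a transcription factor gene of young neurons, had 4746 bases at a CpG ratio of 0.0699. On chromosome X, 484 of 948 genes (51.1%) had a TSS peak, against 66.6% on the autosomes. The mean signal of their TSS peaks was 15.2, against 25.6 in random sets of marked genes of like CpG ratio (permutation test, p = 1.00e-05, the smallest 100000 sets can give). Chromosome X had 1.93 distal peaks per Mb, and the autosomes from 4.15 on chromosome 16 to 9.42 on chromosome 11. Chromosome Y had 4 peaks. Both pools held embryos of mixed sex, and neither the share of males nor the number of copies of X and Y was taken into account. Whether marking per copy differs was therefore not tested.

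Replicate 1's list held 7397 more peaks than replicate 2's, and its peaks were shorter. Weaker enrichment or lower depth in replicate 1 is a candidate cause: at 1-to-1 sites its peak had the lower −log10 q in 94.3% of cases. Wide regions broken into pieces also had the values it needs, since pieces beyond the first within a peak of the other list gave replicate 1 a net surplus of 12338 peaks, 166.8% of the difference. Other tissue in one pool stays open: genes with a TSS peak in replicate 2 only belonged to non-neural lists 2.67 times as often as other genes (6 of 360: Dcn, Myf6, Hba-a2, Cela1, Trp63 and Foxa3; Fisher's exact test, adjusted p = 0.0576), though reads can often not be placed at Hba-a2, and those of replicate 1 only 1.98 times as often (2 of 159, adjusted p = 0.272). Enrichment and depth could not be separated here, and with 1 group no biological explanation was tested.

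Hox genes had fewer bases under H3K4me2 peaks than promoters of like CpG ratio, in each of the 4 clusters taken alone (families Hoxa, Hoxb, Hoxc and Hoxd, 0.252, 0.202, 0.0785 and 0.291 times their matched sets, permutation test, adjusted p at most 0.0231). As a whole they reached 21.3% of their matched sets. This measure defined the pattern, so it is no separate test of CpG content. It counts bases and not strength. The signal was 49.4 at the Hoxa1 peak, 24.0 at Hoxd1 and 12.1 at Hoxa7, against a median of 24.1 over TSS peaks. Reads that cannot be placed are argued against, since 98.7% of 31-mers around Hox TSSs occurred once, against 89.7% around 500 random genes. No biological explanation was tested, as no other tissue was compared.

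The clustered protocadherin genes, whose promoters are chosen cell by cell in neurons, had no peak at any of the 11 Pcdha and 22 Pcdhb TSSs. Of the 12 Pcdhga genes 7 were marked, with 428 bases against 1967 in matched sets (permutation test, adjusted p = 0.0111), and of the 12 non-clustered Pcdh genes 11. Reads shared between family members would need few unique 31-mers, but 90.8% of those around the Pcdha and Pcdhb TSSs occurred once. Their marked length was 0% of that of matched sets, which restates how they were found and is no separate test of CpG content (permutation test, adjusted p = 0.00308 for Pcdha and 0.0111 for Pcdhb). The Hox and clustered protocadherin genes are neighbours, so these p-values are too small. No biological explanation was tested.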
